A study of Mus musculus with 18 samples.

How the data were processed

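RNA was measured in mouse brain by poly(A)-selected sequencing of randomly primed cDNA, in 18 libraries that fall into 3 groups of 6: WT on control diet, 5xFAD on control diet and 5xFAD on a fucose diet, each diet given for 1 month. The labels name the tissue only as brain and give no region, sex, age or batch. They do not say that each library comes from a separate animal, so p-values here measure the spread between libraries and nothing wider. The replicates of a group are not copies of one another: a chi-square per degree of freedom over genes lay between 15.95 and 76.13 in the 45 pairs of replicates.

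The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.3, DESeq2 2.11.40.8 and the mm10 genome build, without giving roles. The gene annotation and the strandedness of counting are not given in the sources used here. The deposited values are normalized counts, a signal made by the authors by dividing the gene counts of each library by 1 size factor, although the table is named as raw counts. Every value was a whole multiple of the smallest positive value of its column (100% of values within a tolerance of 0.001 reads), so the whole reads of each library were recovered. The size factors found in this way equalled median-of-ratios factors computed from the recovered reads to within 4.41e-10%. 2 stray cells beside the Trim65 entry equalled group means (difference 0) and were not used.

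Totals of recovered reads ran from 31.45 to 44.23 M per library (median 38.93 M). In the library with the most reads 1 read was worth 0.886 normalized counts and in the one with the fewest 1.24. A count of 0 in a library allows up to 3 reads, which is 2.66 to 3.72 normalized counts. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

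The table pairs versioned Ensembl identifiers with symbols and positions for 48440 genes. 48058 of these identifiers occur in GENCODE release M21. Positions are written as 1-based mm10 coordinates, and 115 of the 150 genes named by the rule below have identical coordinates in M21. 44 of these 150 genes share exon bases with another annotated gene, 36 of them on the opposite strand, and 9 share over 20% of their exon bases. Because the strandedness of counting is not stated, reads of such neighbours could not be separated.

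The comparisons, lists, tests and alternatives were fixed before the data were examined, for a table of raw counts: edgeR quasi-likelihood tests with TMM. Because the unit is a normalized signal, the reported test is limma 3.58.1 on log2(normalized count + 1), with a pseudocount of 1, a mean-variance trend and robust moderation, in 1 fit of all 18 libraries in R 4.3.3. The test planned first was run as an added alternative on the recovered reads. Genes were kept by filterByExpr of edgeR 4.0.16 on the recovered reads with a minimum count of 10, which left 18808 genes. Adjusted p-values are Benjamini-Hochberg values over the tested genes of a comparison, and a gene is called at a false discovery rate of 0.05. Fold changes come from mean log2 values, so they differ from the ratio of the printed means. Errors of group means are SD and errors of log2 fold changes are moderated standard errors from limma.

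The comparisons made were: 5xFAD against WT on control diet, fucose against control diet in 5xFAD, and 5xFAD on fucose against WT on control diet. WT mice on fucose are not among the groups, so an interaction of genotype and diet is not analysed here. 36 gene lists of cell types, brain regions and pathways were written down before the data were examined. 35 of them were tested with camera of limma at a preset correlation of 0.01 between genes, with adjustment over the 35 lists of a comparison, and the sex-linked list was only described. Each list was also tested with the correlation estimated from the data and with fry, a rotation test of whether the genes of a list move on balance 1 way. Some lists share genes, such as Itgax in the disease-associated microglia and complement lists and Ctsz in the disease-associated microglia and lysosome lists. The score of a list in a library is the mean log2 value of its tested members, compared between groups with 2-sided exact permutation tests.

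Genes were named by a rule fixed in advance. It takes genes of the transgenes, such as App and Thy1, the 10 higher and 10 lower called genes with the largest log2 fold change in each of the first comparisons (5 and 5 in the third), or the 10 smallest p-values where fewer than 10 genes were called, and up to 4 members with the smallest p-values of each called list and of 7 lists chosen for the question (2 members in the third comparison). Predicted genes with clone-like symbols and sex-linked genes were left out of each ranking. Genes with a mean under 1 CPM in the higher group were left out of the ranking by log2 fold change, but not of that by p-value. Some genes that the rule takes are not reported here. A gene named outside this rule is marked as chosen after its values were seen.

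The genotype and diet comparisons share the 5xFAD control libraries, which pushes their correlation below 0. The correlation was therefore compared with 100 simulated sets without effects and with the mean over 20 arrangements in which the 6 shared libraries were split into 2 sets of 3, each set serving 1 comparison. The alternatives tried were no filter on low counts, a mean of at least 1 CPM, fits of only the groups compared, the replicate number as a block, Xist as a covariate, 1 surrogate variable (sva 3.50.0), edgeR with RLE factors, DESeq2 1.42.0, voom with sample quality weights, and each library left out in turn. edgeR with TMM, planned first as the test, was made an alternative once the unit was known. Added after the data were seen were pseudocounts of 0.5 and 10, TMM scaling, leaving out the 3 libraries with little Xist, and the mean of the ribosomal protein and oxidative phosphorylation genes as a covariate.

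The procedure was tested on simulated data with the same 18808 genes and group sizes, with counts drawn independently for each gene. Of 50 genes changed 2-fold it called 78% in the first comparison, 68% in the second and 72% in the third, and of 50 changed 1.5-fold 52%, 50% and 50%, with 0 in the wrong direction. A list raised 1.5-fold was called in the first and second comparisons with 1 other list beside it in each. False calls of genes were 6 of 131, 14 of 249 and 8 of 116. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used to prepare tables and draw figures.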

Results

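RNA of mouse brain was sequenced in 18 libraries, 6 from WT mice on control diet, 6 from 5xFAD mice on control diet and 6 from 5xFAD mice on a fucose diet, after 1 month of the diet. 5xFAD mice carry human transgenes with mutations of familial Alzheimer's disease, expressed from elements of the mouse Thy1 gene. Fucose is a sugar that cells attach to glycoproteins. The totals averaged 38.98 ± 4.73 M reads in the WT control group, 39.7 ± 3.499 M in the 5xFAD control group and 38.33 ± 2.47 M in the 5xFAD fucose group (SD, n = 6 each). In each group 1 of 6 libraries had little Xist, the transcript of the inactive X chromosome: 11.7 normalized counts in WT control replicate 4, 6.60 in 5xFAD control replicate 5 and 0 in 5xFAD fucose replicate 5, where 0 allows up to 2.95. All other libraries had at least 7251 normalized counts of Xist, and the same 3 libraries had 1641 to 1797 normalized counts of the Y-linked gene Ddx3y.

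The first comparison asks which brain transcripts differ between 5xFAD and WT mice on control diet. Genes of microglia, the macrophages of the brain, showed the largest increases. Cst7 (ENSMUSG00000068129.5, chromosome 2, 150570415 to 150578944, plus strand), which encodes an inhibitor of lysosomal proteases, rose from 21.2 ± 9.96 normalized counts in WT to 2655 ± 704 in 5xFAD (SD, n = 6 per group), a 128-fold change. Clec7a (ENSMUSG00000079293.11, chromosome 6, 129461591 to 129472779, minus strand), a receptor for beta-glucans on myeloid cells, rose 17.0-fold from 35.9 ± 7.55 to 627 ± 129.7. Gfap (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912, minus strand), the intermediate filament of astrocytes, rose 5.87-fold from 14692 ± 3166 to 85049 ± 12097. For each of these genes all 6 5xFAD libraries lay above the highest WT library.

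Disease-associated microglia, a list of genes that rise in microglia around amyloid plaques, had a median log2 fold change of 1.63 over 27 measured members. 24 of them rose over all genes and 26 when adjusted over the list alone, and 3 were not called (camera adjusted p = 5.44e-67). Its members with the smallest p-values were Clec7a, Cst7, the lysosomal protease gene Ctsz (log2 fold change 1.48 ± 0.11 SE) and the integrin gene Itgax (4.70 ± 0.32 SE). Homeostatic microglia, a list of identity genes of resting microglia, rose with a median of 0.72 (adjusted p = 4.80e-13). 6 of its 14 members rose, and 8 when adjusted over the list alone. Among them were Cx3cr1 (0.96 ± 0.16 SE) and Csf1r (0.85 ± 0.084 SE), the receptor for the growth factor on which microglia depend. Csf1r shares 15.1% of its exon bases with Hmgxb3 on the opposite strand.

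The complement list, proteins and receptors of a cascade that tags material for uptake, rose with a median of 1.02 (adjusted p = 1.54e-23). 9 of its 15 measured members rose and 12 when adjusted over the list alone, among them C3ar1 (2.34 ± 0.16 SE), Itgb2 (1.41 ± 0.12 SE) and C1qc (1.40 ± 0.12 SE). The lysosome list rose with a median of 0.54 (adjusted p = 4.64e-41): 18 of 31 members rose, and 23 when adjusted over the list alone. Ctss (1.46 ± 0.10 SE), Laptm5 (1.46 ± 0.11 SE) and Man2b1 (1.09 ± 0.086 SE) were among them. The reactive astrocyte list rose with a median of 1.22 (adjusted p = 3.17e-24). 12 of its 20 members rose and 13 when adjusted over the list alone, with Serpina3n (2.84 ± 0.22 SE), Aspg (1.72 ± 0.15 SE) and the filament gene Vim (1.43 ± 0.14 SE) beside Gfap. These 5 lists kept their calls with an estimated correlation, at adjusted p-values of 0.000124, 0.0399, 2.28e-05, 0.000266 and 0.00141 in the order named here. The mean score of each of the 5 lists was higher in all 6 5xFAD control libraries than in any WT library (exact permutation p = 0.00216, the smallest that 6 against 6 can give, and 0.0152 after adjustment over 35 lists).

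**Figure D1:**
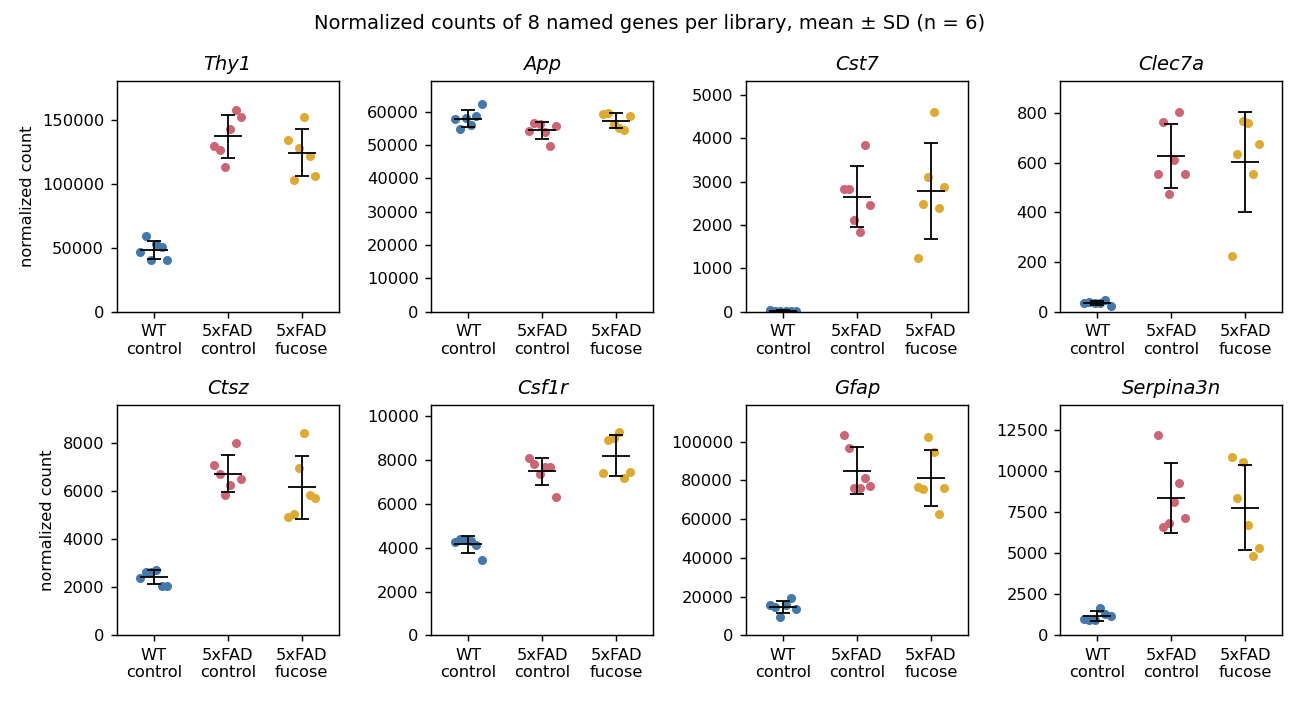
Normalized counts (vertical axes, starting at 0) of Thy1, App, Cst7, Clec7a, Ctsz, Csf1r, Gfap and Serpina3n in each library, with points for the 6 libraries of each group and bars for the mean ± SD. Thy1 averaged 48310 in WT control, 137014 in 5xFAD control and 124341 in 5xFAD fucose, whereas App averaged 57890, 54366 and 57262. Thy1 counts may include transgene transcripts that hold Thy1 sequence, and App is the mouse gene.

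Other lists called at the preset correlation lost that call when the correlation was estimated. The interferon response list had a median of 0.61 (adjusted p = 1.10e-06, and 0.540 with an estimated correlation), with 0 of 24 members called by limma over all genes and 6 higher when adjusted over the list alone. Ifi27 was at 0.46 ± 0.12 SE (adjusted p = 0.0507) and Bst2 at 0.86 ± 0.26 SE (adjusted p = 0.122). Ifi27 passed in 13 of 27 alternatives, among them edgeR and DESeq2 (adjusted p from 0.0134 to 0.134 over all 27). Antigen presentation had a median of 0.41 (adjusted p = 0.000845, and 0.541 with an estimated correlation). 2 of its 15 members rose, B2m (0.91 ± 0.14 SE), the light chain of class I molecules, and the immunoproteasome gene Psmb8 (0.93 ± 0.22 SE), and 5 did when adjusted over the list alone. The call of Psmb8 was lost without WT control replicate 3 or 5xFAD control replicate 4 or 6 (highest adjusted p = 0.0664). Cholesterol synthesis had a median of 0.18 (adjusted p = 0.000159, and 0.405 with an estimated correlation). Of its 20 members only Fdft1, squalene synthase, was called (0.35 ± 0.077 SE), and 4 were when adjusted over the list alone. Fdft1 shares 18.3% of its exon bases with Ctsb on the opposite strand. Cytosolic ribosomal proteins had a median of 0.18 (adjusted p = 6.15e-10, and 0.643 with an estimated correlation), with 0 of 77 members called over all genes or over the list alone, Rplp0 at 0.25 ± 0.093 SE and Rpl22 at 0.22 ± 0.080 SE. The mean score of this list differed by 0.18 with all libraries, by 0.11 without 5xFAD control replicate 5 and by 0.12 without WT control replicate 6. That of antigen presentation differed by 0.26, by 0.17 without 5xFAD control replicate 4 and by 0.047 without 5xFAD control replicate 6.

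Lists of synaptic genes were lower at the preset correlation without any called member. The postsynaptic glutamatergic list, receptors and scaffolds of excitatory synapses, had a median of -0.13 (adjusted p = 0.000661, and 0.296 with an estimated correlation), with Shank3 at -0.36 ± 0.12 SE and Dlg4 at -0.18 ± 0.093 SE among its 22 members. GABA-A receptors had a median of -0.10 over 13 members (adjusted p = 0.0235, and 0.382 with an estimated correlation). Presynaptic release genes had a median of -0.058 over 20 members (adjusted p = 0.0289, and 0.540 with an estimated correlation), with Cplx1 at -0.18 ± 0.082 SE and Syn1 at -0.12 ± 0.062 SE. Immediate-early genes, which neurons induce upon activity, had a median of -0.41 over 16 members (adjusted p = 0.0267, and 0.751 with an estimated correlation), with Npas4 at -0.63 ± 0.34 SE. Endothelial cell markers had a median of -0.12 over 12 members (adjusted p = 0.0289, and 0.296 with an estimated correlation). Heat shock genes had a median of -0.13 over 10 members (adjusted p = 0.0411, and 0.541 with an estimated correlation), with Hsph1 lower when adjusted over the list alone (-0.30 ± 0.087 SE). In these lists 0 members passed over all genes by limma, and apart from Hsph1 0 passed when adjusted over the list alone. The mean score of immediate-early genes differed by -0.35, by -0.12 without 5xFAD control replicate 2, -0.61 without WT control replicate 1 and -0.21 without WT control replicate 6, that of presynaptic release by -0.067 and by -0.040 without WT control replicate 2, and that of heat shock by -0.12 and by -0.057 without WT control replicate 5.

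The mouse gene App (ENSMUSG00000022892.10, chromosome 16, 84954440 to 85173707) was not called (log2 fold change -0.091, SE 0.056, adjusted p = 0.578). Thy1 (ENSMUSG00000032011.4, chromosome 9, 44043384 to 44048579, plus strand), whose elements drive the transgenes, rose 2.84-fold from 48310 ± 7221 to 137014 ± 16819 normalized counts (SD, n = 6 per group, adjusted p = 1.26e-09). The only genome build named is that of the mouse, so expression of the human transgenes was not measured on its own. Thy1 counts may include transgene transcripts that hold Thy1 sequence, so a rise of the Thy1 gene itself is not shown. App counts likewise do not give the level of the human transgene. In the list of fucose metabolism and fucosylation, 1 of 17 measured members rose, over all genes and over the list alone: Fuca1 (ENSMUSG00000028673.10, chromosome 4, 135920735 to 135940311), a lysosomal enzyme that removes fucose from glycoproteins, went from 1938 ± 199 to 2622 ± 225 (log2 fold change 0.44 ± 0.084 SE, adjusted p = 0.00248). The list as a whole was not called (median -0.016, adjusted p = 0.587), with Fut9 at -0.29 ± 0.11 SE and Fut8 at -0.20 ± 0.080 SE. Notch signalling, a pathway whose receptors carry fucose, was not called either (median -0.044, adjusted p = 0.525), with 0 of 22 members called by limma over all genes or over the list alone and Mfng at 0.38 ± 0.16 SE.

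Genes that fell were fewer. Rnase1 (ENSMUSG00000035896.4, chromosome 14, 51145002 to 51146767), a secreted ribonuclease, fell from 49.5 ± 10.7 to 14.6 ± 9.93 normalized counts (log2 fold change -1.90, SE 0.41, adjusted p = 0.00918). Hbegf, a growth factor gene, fell from 539 ± 79.0 to 335 ± 59.6 (-0.69 ± 0.15 SE), Chsy3, a chondroitin sulfate synthase gene, had a log2 fold change of -0.91 ± 0.21 SE, and Apln, the gene of the peptide apelin, one of -0.73 ± 0.16 SE. Akr1c14 (-1.82, adjusted p = 0.0463), Hs6st3 (-1.25, adjusted p = 0.0364), Lgr6 (-1.003, adjusted p = 0.0390), Hmcn1 (-0.9999, adjusted p = 0.0413), Thbd (-0.78, adjusted p = 0.0406) and Shc3 (-0.78, adjusted p = 0.0230) also passed, and each of these 6 calls was lost without some single libraries, from 4 of 12 for Shc3 to 9 of 12 for Akr1c14.

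In all, limma called 402 of 18808 genes, 371 higher and 31 lower in 5xFAD, of which 200 and 9 changed by more than 2-fold. The number of lower genes depended on single libraries: it was 52 without WT control replicate 4, 18 without 5xFAD control replicate 5, 19 without WT control replicate 6 or 5xFAD control replicate 1 or 4, and 20 without 5xFAD control replicate 6. DESeq2 gave 477 higher and 85 lower genes. 2150 genes had an unadjusted p under 0.05, where 940.4 are expected by chance. The libraries of the 2 groups did not overlap for 389 genes, where chance gives 0.216% of genes or 40.71, and 304 of the called genes were among them. Among the remaining genes with the largest increases, Ccl3 had a log2 fold change of 4.14 ± 0.58 SE, Gpnmb 3.96 ± 0.27 SE and Hcar2 3.87 ± 0.56 SE (2.70 to 4.11 over the alternatives). Ctse was called too, but its WT mean of 1.26 normalized counts lies under what 0 reads allow, and the size of its change depends on the pseudocount (2.30 to 5.28 over the alternatives). Lilrb4a was also among them (3.77 ± 0.35 SE), a gene with close paralogs whose reads cannot be told apart here. It also shares 92.8% of its exon bases, on the same strand, with a second annotated entry of the same name.

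The second comparison asks what 1 month of fucose diet changed in 5xFAD brain. Among the genes that set 5xFAD apart from WT, Clec7a averaged 627 ± 129.7 normalized counts on control diet and 603 ± 202 on fucose, Gfap 85049 ± 12097 and 81389 ± 14520, and Cst7 2655 ± 704 and 2786 ± 1103 (SD, n = 6 per group), differences smaller than the spread between libraries. limma called 0 of 18808 genes, with 1005 at an unadjusted p under 0.05 where 940.4 are expected by chance, and a smallest adjusted p of 0.822. edgeR with RLE and with TMM factors, DESeq2 and voom also called 0 genes, with 953, 948, 1035 and 1749 at an unadjusted p under 0.05. By limma with 1 library left out, that number ran from 547 without 5xFAD control replicate 5 to 1505 without 5xFAD fucose replicate 4. With the mean of the ribosomal protein and oxidative phosphorylation genes as a covariate it was 435. Libraries of the 2 diets did not overlap for 35 genes, where chance gives 40.71. The 95% interval of the change lay inside 2-fold for 14659 genes (77.9%) and inside 1.5-fold for 11526 (61.3%). In simulated data of this size 68% of 2-fold, 50% of 1.5-fold and 10% of the smallest simulated changes were called in this comparison. That simulation called 249 genes in all, which eases the adjusted threshold, and drew counts independently for each gene. With 0 genes called here, the share of single changes that could be found is likely lower.

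Cytosolic ribosomal proteins and nuclear oxidative phosphorylation genes, the subunits of the ribosome and of the respiratory chain, were lower on fucose at the preset correlation. The ribosomal list had a median log2 fold change of -0.20 over 77 members (adjusted p = 3.17e-17, and 0.952 with an estimated correlation), with Rpl19 at -0.24 ± 0.10 SE. Its higher level in 5xFAD than in WT and its lower level on fucose both rest on the same 5xFAD control libraries, so they are not separate findings. In 5xFAD on fucose against WT the ribosomal list had a median of -0.0033 and was not called (camera adjusted p = 0.681 at the preset correlation). The oxidative phosphorylation list had a median of -0.18 over 70 members (adjusted p = 3.12e-16, and 0.952 with an estimated correlation), with Ndufc2 at -0.25 ± 0.10 SE and Cox7b at -0.24 ± 0.094 SE. Markers of oligodendrocyte precursors were higher, with a median of 0.15 over 10 members (adjusted p = 0.0314, and 0.521 with an estimated correlation), Neu4 at 0.39 ± 0.15 SE and Bmp4 at 0.57 ± 0.23 SE. 0 members of the 3 lists were called by limma, over all genes or when adjusted over the list alone. Compared as 1 score per library, the ribosomal list differed by -0.20 (exact permutation p = 0.0844), the oxidative phosphorylation list by -0.17 (exact permutation p = 0.108) and the precursor list by 0.20 (exact permutation p = 0.0152, and 0.530 after adjustment over 35 lists). Without 5xFAD control replicate 5 the first 2 of these differences were -0.13 and -0.11. The precursor call was also lost without 5xFAD control replicate 6 or 5xFAD fucose replicate 4 (highest adjusted p = 0.0779).

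**Figure D2:**
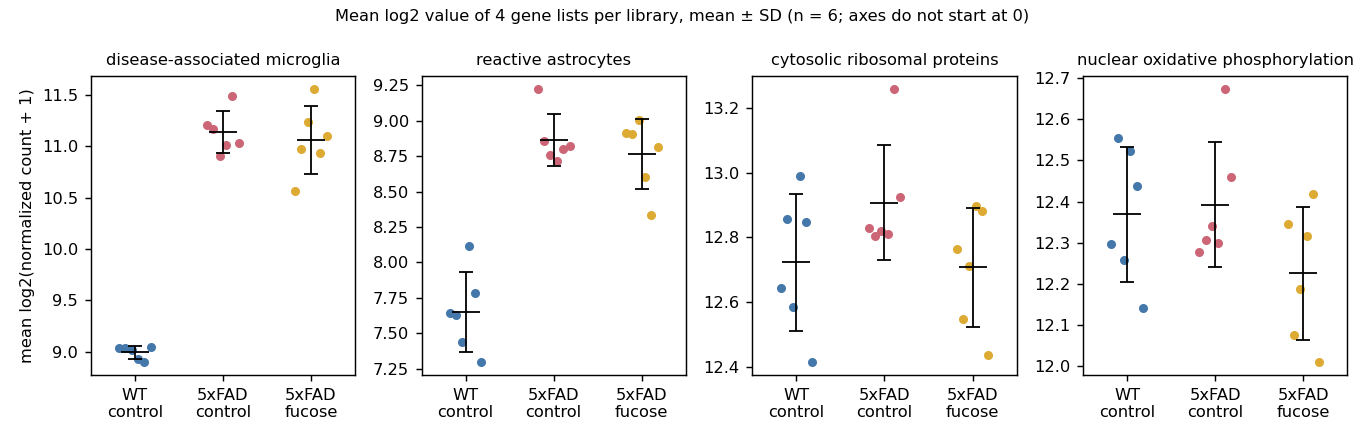
Mean log2(normalized count + 1) of the members of 4 gene lists (vertical axes, not starting at 0) in each library, with points for the 6 libraries of each group and bars for the mean ± SD. The disease-associated microglia score averaged 8.997 in WT control, 11.13 in 5xFAD control and 11.06 in 5xFAD fucose, and the ribosomal score 12.72, 12.91 and 12.71.

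The lists closest to the treatment did not pass. Fucose metabolism and fucosylation had a median of 0.030 (adjusted p = 0.883), with 0 of 17 members called over all genes or over the list alone, Fuca1 at -0.18 ± 0.084 SE, Pofut2 at -0.20 ± 0.12 SE and Fut8 at 0.12 ± 0.080 SE. Notch signalling had a median of 0.039 (adjusted p = 0.494) over 22 members, with Notch1 at 0.53 ± 0.18 SE and its target Hes1 at -0.26 ± 0.13 SE. The presynaptic release list had a median of 0.018 (adjusted p = 0.814), with Vamp2 at -0.17 ± 0.083 SE, and the postsynaptic glutamatergic list one of 0.011 (adjusted p = 0.530), with Shank2 at 0.24 ± 0.11 SE. Immediate-early genes had a median of -0.41 (adjusted p = 0.149), with Junb at -0.60 ± 0.48 SE and Arc at -0.79 ± 0.65 SE. Disease-associated microglia had a median of -0.11 (adjusted p = 0.408). In that list 0 of 27 members passed over all genes and 1 fell when adjusted over the list alone: Lpl (ENSMUSG00000015568.15, chromosome 8, 68880491 to 68907448), lipoprotein lipase, at 1618 ± 138 normalized counts on control diet and 1260 ± 150.1 on fucose (log2 fold change -0.37 ± 0.10 SE, adjusted p over all genes = 0.822). Reactive astrocytes had a median of -0.082 (adjusted p = 0.370), with Ggta1 at -0.35 ± 0.15 SE. Single libraries moved these values: the mean score of reactive astrocytes differed by -0.099 with all libraries, -0.028 without 5xFAD control replicate 1 and -0.014 without 5xFAD fucose replicate 5. That of immediate-early genes differed by -0.32, and by -0.55 without 5xFAD control replicate 2, -0.51 without 5xFAD fucose replicate 5, -0.19 without 5xFAD control replicate 5 or 5xFAD fucose replicate 4 and -0.15 without 5xFAD fucose replicate 6. That of disease-associated microglia differed by -0.073, from -0.17 without 5xFAD fucose replicate 4 to 0.027 without 5xFAD fucose replicate 1. The scores of fucose metabolism and fucosylation (-0.024 to 0.016) and presynaptic release (-0.014 to 0.013) also changed sign with 1 library left out, while those of Notch signalling (0.023 to 0.067) and postsynaptic glutamatergic genes (0.0065 to 0.060) did not. In these lists other than disease-associated microglia, 0 members were called by limma, over all genes or over the list alone.

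The 10 genes with the smallest p-values, none past the threshold, all had an adjusted p of 0.822. The largest among them in expression were Lpl, Med31, a Mediator subunit gene (-0.39 ± 0.10 SE), and Bcl3, a regulator of NF-kappa-B (-0.95 ± 0.25 SE). The others were Zfp648 (1.59 ± 0.37 SE), Zbtb11os1 (-0.68 ± 0.18 SE), Zfp119a (-0.72 ± 0.20 SE), Tbx15 (1.12 ± 0.31 SE) and M6pr-ps (2.48 ± 0.65 SE), with Fam229a and Plin1 at means of 2.81 and 4.29 normalized counts on fucose. The changes of M6pr-ps (1.13 to 2.83 over the alternatives) and Zfp648 (1.01 to 1.74) depend on the pseudocount, as they rest on few reads. Med31 and Zbtb11os1 share 26.3% and 36.2% of their exon bases with a gene on the opposite strand. App (0.075 ± 0.056 SE) and Thy1 (-0.14 ± 0.11 SE) were not called.

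**Figure D3:**
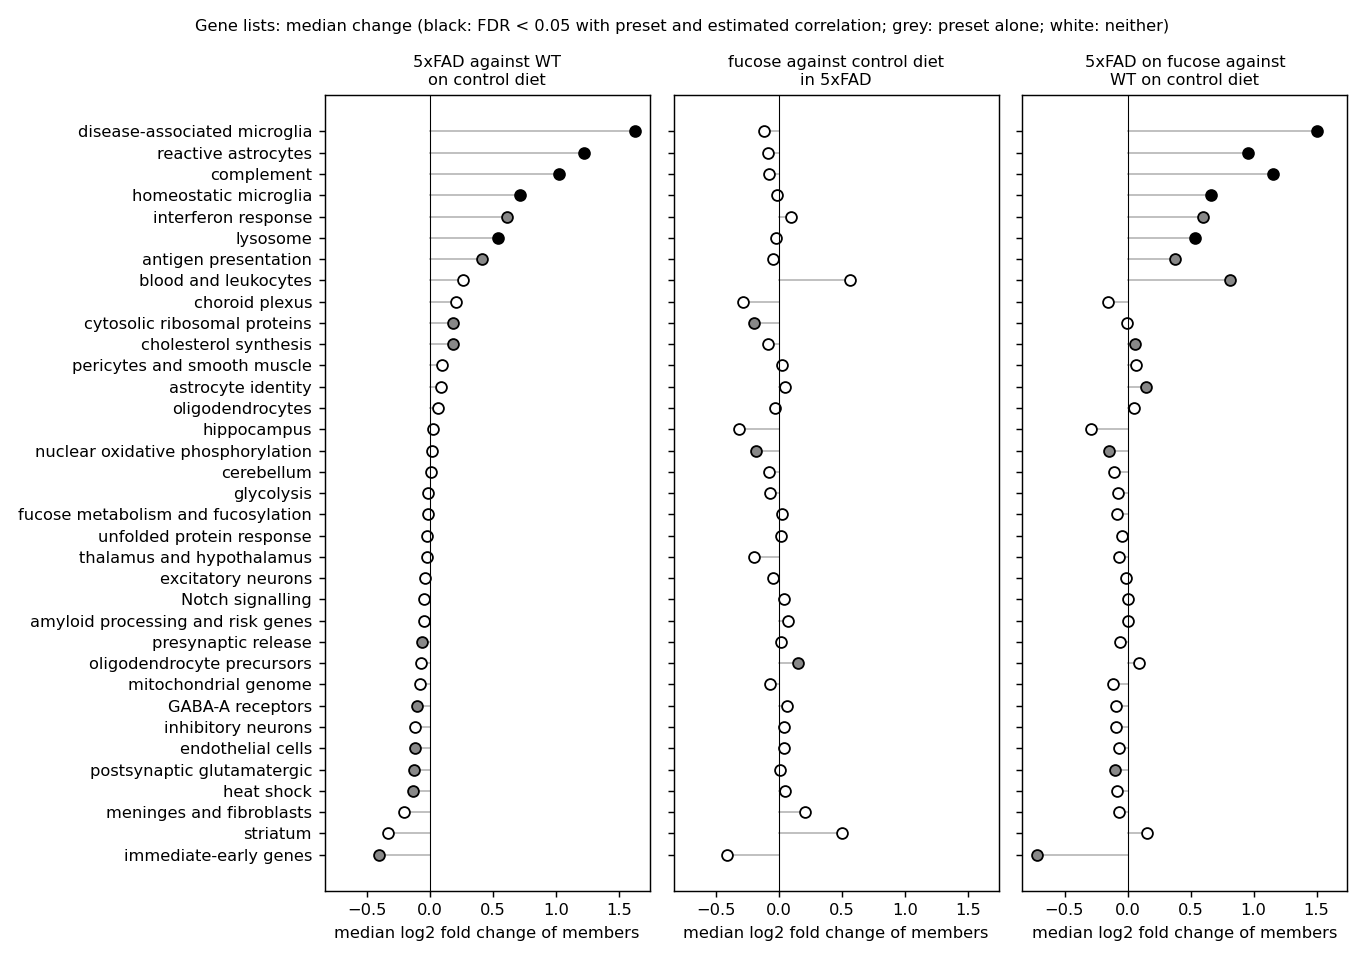
Median log2 fold change of the members of 35 gene lists (horizontal axes) in each comparison, with black points for lists called with preset and with estimated correlation, grey for those called with the preset alone and white for the others. The medians of disease-associated microglia were 1.63, -0.11 and 1.501 in the order of the panels.

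Whether fucose moved the genotype-dependent genes back was compared over genes, which are not independent replicates. Of the 402 genes called in 5xFAD against WT, 282 (70.1%) had a diet change of opposite sign: 252 of the 371 higher and 30 of the 31 lower genes. The median diet log2 fold change was -0.080 for the higher genes, whose median genotype change was 1.05, and 0.27 for the lower genes, whose median genotype change was -0.58. The lower genes were not compared with simulated sets on their own. 35 of the 402 had an unadjusted diet p under 0.05, and the smallest adjusted p over these genes alone was 0.0909. Because both comparisons use the same 5xFAD control libraries, a share over 50% needs no diet effect: sets simulated with genotype effects and no diet effect gave a mean of 56.2% (19.5 to 83.2% in 50 sets). With the shared libraries split into 2 sets of 3 the share was 61.2% (45.1 to 75% over 20 arrangements), over a mean of 269 genes called with 3 instead of 6 5xFAD control libraries. Over all tested genes the correlation of genotype and diet changes was -0.42, within the simulated range without effects (mean -0.49, from -0.71 to -0.12), and -0.045 with the shared libraries split. The covariance was -0.0596 observed, -0.0556 simulated and -0.00861 split.

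**Figure D4:**
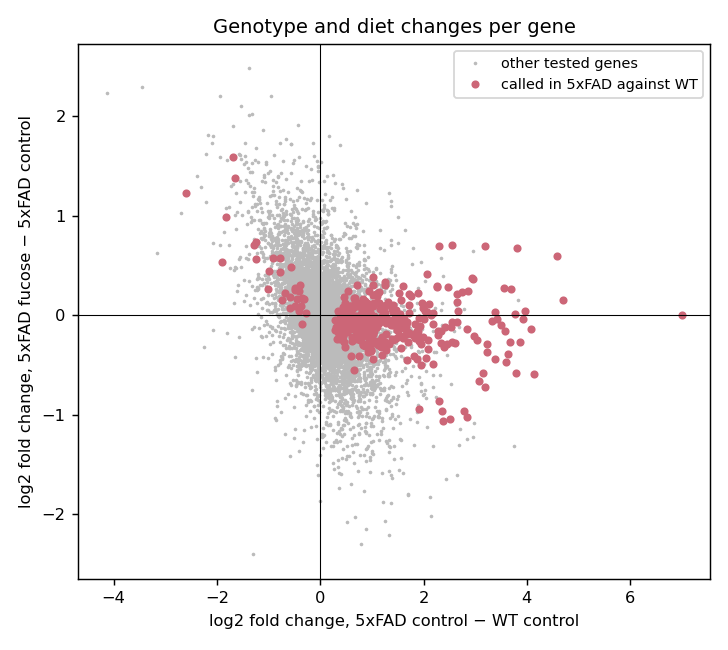
Log2 fold change of fucose against control diet in 5xFAD (vertical axis) against that of 5xFAD against WT on control diet (horizontal axis) for 18808 tested genes, with the 402 genes called between genotypes in red. The downward tilt of the grey points carries a correlation of -0.42, which the shared 5xFAD control libraries also give without effects (simulated mean -0.49).

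The third comparison asks how 5xFAD brain after fucose differs from WT brain on control diet. The microglial, lysosomal and astrocytic genes were again higher. Cst7 averaged 2786 ± 1103 normalized counts against 21.2 ± 9.96 in WT (SD, n = 6 per group; log2 fold change 7.01 ± 0.32 SE), Itgax 845 ± 479 against 25.0 ± 7.16 (4.85 ± 0.32 SE) and Gfap 81389 ± 14520 against 14692 ± 3166 (2.48 ± 0.14 SE). Thy1 rose 2.57-fold (adjusted p = 7.47e-09), whereas App (log2 fold change -0.015, SE 0.056, adjusted p = 0.960) did not pass. Here too, transgene transcripts were not separated from those of the mouse genes.

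Disease-associated microglia rose with a median of 1.501 (adjusted p = 1.45e-67), 25 of 27 members over all genes and 26 when adjusted over the list alone. The lysosome list rose with a median of 0.53 (adjusted p = 5.81e-44; 20 of 31 members, 24 when adjusted over the list alone), with Ctss at 1.46 ± 0.10 SE and Laptm5 at 1.36 ± 0.11 SE. Complement rose with a median of 1.15 (adjusted p = 2.44e-24; 9 of 15 members, 12 over the list alone), with C3ar1 at 2.18 ± 0.16 SE. Reactive astrocytes rose with a median of 0.95 (adjusted p = 7.97e-24; 11 of 20 members, 14 over the list alone), with Aspg at 1.82 ± 0.15 SE. Homeostatic microglia rose with a median of 0.66 (adjusted p = 5.15e-13; 6 of 14 members, 10 over the list alone), with Csf1r at 0.98 ± 0.084 SE. These 5 calls held with an estimated correlation, at adjusted p-values from 1.78e-05 for complement to 0.0402 for homeostatic microglia.

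Another 8 lists were called at the preset correlation and lost the call with an estimated one. Higher were interferon response (median 0.60; adjusted p = 0.425 with an estimated correlation), antigen presentation (0.38; adjusted p = 0.576 with an estimated correlation), astrocyte identity (0.15; adjusted p = 0.275 likewise), blood and leukocytes (0.81; adjusted p = 0.280 likewise) and cholesterol synthesis (0.057; adjusted p = 0.636 likewise). Lower were immediate-early genes (-0.72; adjusted p = 0.552 likewise), postsynaptic glutamatergic genes (-0.10; adjusted p = 0.425 likewise) and nuclear oxidative phosphorylation (-0.15; adjusted p = 0.576 likewise). Their called members were B2m (0.88 ± 0.14 SE) and H2-D1 (1.06 ± 0.20 SE) of antigen presentation and the astrocyte membrane gene Mlc1 (0.27 ± 0.067 SE). Oas1a stood at 1.71 ± 0.47 SE (adjusted p = 0.0675), S100a8 at 2.91 ± 0.84 SE (adjusted p = 0.0886; 1.13 to 3.85 over the alternatives, since it has few reads), Dusp1 at -0.86 ± 0.35 SE, Dlg4 at -0.26 ± 0.093 SE and Atp5d at -0.31 ± 0.10 SE. The call of antigen presentation was lost without 5xFAD fucose replicate 5 (adjusted p = 0.137), and that of cholesterol synthesis without any 1 of 6 of the 12 libraries (highest adjusted p = 0.274). The mean score differed by 0.26 for antigen presentation and by 0.085 without 5xFAD fucose replicate 5, and by 0.13 for cholesterol synthesis and by 0.081 without 5xFAD fucose replicate 4.

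Limma called 376 genes in this comparison, 359 higher and 17 lower, of which 190 and 0 changed by more than 2-fold, and 2043 genes had an unadjusted p under 0.05. The number of lower genes was not stable: without WT control replicate 1, 2, 4, 5 or 6 it was 32, 8, 8, 9 and 35, and without 5xFAD fucose replicate 1, 2, 3, 5 or 6 it was 11, 5, 6, 76 and 7. DESeq2 gave 449 higher and 58 lower genes. Lower were Nppc (-0.73, adjusted p = 0.0359), Btbd17 (-0.68, adjusted p = 0.0355), Sac3d1 (-0.54, adjusted p = 0.0256), Igsf21 (-0.51, adjusted p = 0.0410) and Foxp2 (-0.50, adjusted p = 0.0376), each of whose calls was lost without 7 or 8 of the 12 single libraries, as was that of Mlc1 without 7. 306 of the called genes were also called, in the same direction, in 5xFAD against WT on control diet, where 7.08 higher and 0.028 lower shared genes are expected if the calls were independent. Both comparisons use the WT libraries. With the WT libraries split into 2 sets of 3 a mean of 184 genes was shared (168 to 201), of a mean of 310 and 283 called with 3 WT libraries per comparison. The correlation of the changes was 0.73, within the simulated range without effects (mean 0.50, from 0.26 to 0.77), and 0.30 with the WT libraries split. The covariance was 0.137 observed, above the simulated range without effects (mean 0.0577, from 0.0261 to 0.0955). With the WT libraries split the covariance was 0.0751. The difference between the third and the first comparison is the diet comparison itself, in which 0 genes passed, so the 96 and 70 genes called in 1 of the comparisons alone are not shown to differ between diets.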

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

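The tests of a higher share of microglia, of the spread between libraries, of transcript length and of single libraries were chosen only after the results they concern were seen, and the test of transcript length was divided into part and whole source after its first form had met both of its bounds. Values are listed here because the highest or lowest of 6 libraries of a group lay apart from the other 5 by more than a share of 0.625 of the whole range of the group. Chance gives this in about 1 of 20 groups. 450 groups of named genes, together with those of Xist, which lie outside the 450, gave 32 such values. For the 450 alone 22.5 are expected. 105 groups of list scores gave 8.

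5xFAD control replicate 5 held 11 of these values. Among them, it had the highest normalized counts of its group for Rpl39 (5561), Rpl19 (10658), Rps15 (20323), Rpl18 (10112), Sncb (37564) and Cox5a (3681), and the lowest for App (49607), Apln (401) and Xist (6.60). Its ribosomal protein score was the highest of its group, at 13.26 against 12.93 for the next library. The other low values of Xist were 11.7 in WT control replicate 4 and 0 in 5xFAD fucose replicate 5.

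Among microglial and vascular genes, WT control replicate 6 was lowest for Csf1r (3417), Itgb2 (249) and Thbd (301), WT control replicate 2 for Ccl3 (2.29) and Hcar2 (0), WT control replicate 1 for Cdh5 (362), WT control replicate 5 for Tie1 (380.17) and 5xFAD fucose replicate 1 for Clec7a (224). Lpl was highest in 5xFAD control replicate 6 (1885) and Plin1 in 5xFAD control replicate 1 (28.9). Among other genes, WT control replicate 1 was lowest for Arc (2857), Gpr17 (869) and Dll4 (77.8), 5xFAD control replicate 2 for Arc (2420), 5xFAD control replicate 4 for Cplx1 (31651), WT control replicate 3 for Hspa8 (54994), 5xFAD fucose replicate 1 for Nrarp (97.3) and 5xFAD fucose replicate 3 for Fam229a (0). Rfng was highest in 5xFAD fucose replicate 5 (4805). Nrarp shares 79.4% of its exon bases with a gene on the opposite strand.

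Among list scores, WT control replicate 3 was lowest for hippocampus (8.21, with the others from 9.73 to 9.92) and cerebellum (7.74) and highest for homeostatic microglia (9.70). 5xFAD control replicate 3 was lowest for thalamus and hypothalamus (7.76, with the others from 9.69 to 10.54) and for the unfolded protein response (10.57). WT control replicate 6 was highest for interferon response (8.44) and 5xFAD control replicate 1 for reactive astrocytes (9.22).

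Other splits of the same libraries were compared with the real groups, 100 splits per comparison. For 5xFAD against WT on control diet the real split alone gave as many genes (402, highest other 38), which makes chance unlikely for the gene count. It does not exclude chance, since only 100 of the possible splits were compared. For the lists, 17 of 100 splits gave as many (15, highest other 19), so chance is not excluded for the number of lists. For the diet comparison the real gene count is 0, which all 100 splits match by definition (highest other 0), so the gene count tells nothing about chance. There, 99 of 100 splits gave as many lists as the real 3 (highest other 17), so chance is not excluded for the number of lists. For 5xFAD on fucose against WT 2 of 100 splits, the real split among them, gave as many genes (376). That share is low, but the other split gave more genes than the real groups. The gene count alone therefore does not exclude chance or sample structure in this comparison. The other split called 1033 genes, which points to a structure of the samples: it parted each of the 2 groups at the median of its ribosomal protein score (mean score of ribosomal and oxidative phosphorylation genes 12.37 against 12.66), and the next highest split gave 44. With that score as a covariate, added after this was seen, 445 genes were called in that comparison, 453 in the first and 0 in the diet comparison. The number of lists in the third comparison was matched by 30 of 100 splits (13, highest other 21), so chance is not excluded for it.

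The higher microglial and lysosomal genes in 5xFAD were set against 3 technical explanations. A difference in depth is argued against by thinning every library to 31.45 M reads, after which 94.8% of the 402 genes (381) were called. Uneven brain region content is argued against by a fit with the striatum, diencephalon and choroid plexus scores as covariates, in which the median of disease-associated microglia was 102% of that without them and 344 genes were called. A larger share of microglia with unchanged transcripts, as the whole source, is argued against by the difference of the disease-associated and homeostatic scores, which was higher in 5xFAD by 1.497 on the log2 scale (2-sided exact permutation p = 0.00216). As a hypothesis found and tested on the same data, the 5xFAD genotype may change transcripts within microglia, and a change in their share besides stays open.

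The absence of called genes with fucose was set against hidden structure, swapped labels and spread. Fits with 2 or 3 surrogate variables called at most 0 genes, which argues against hidden structure of that form. Each of the 36 exchanges of a control-diet and a fucose library also called 0. That argues only against 1 swapped pair that hid changes large enough to be called. With a small diet effect or none, a swapped pair would give the same result, so a swap as such is not excluded. The spread between libraries stays open as a reason for missing changes of 2-fold, since 77.9% of genes had a 95% interval inside 2-fold, a share between the bounds set for either reading. Among the 402 genotype genes it was 84.3% (339). A biological reason, such as a small effect of the diet on brain transcripts after 1 month, was not tested apart from these.

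The lower ribosomal protein and oxidative phosphorylation genes with fucose came to -0.18 in a joint score of 147 genes (2-sided exact permutation p = 0.0909), so the pattern itself does not pass a test between libraries. The joint score fell below that of genes matched in exon length and expression by a difference of -0.085 (exact permutation p = 0.0455). That met the bound set against transcript length as the whole source, but cannot exclude it. The lists were picked because they were lower in these same libraries, and the length matched was that of all annotated exons of a gene. The largest gap between the scores was in 5xFAD control replicate 5, at 12.98 against 12.76. Length as part of the source stays open too, since the matched genes had a median of -0.11 (score change -0.10, exact permutation p = 0.139). Brain region content stays open: with region scores as covariates the change was -0.22 with a 95% interval from -0.47 to 0.032. The weight of 1 library stays open too, since the change was -0.12 without 5xFAD control replicate 5 (65.6% of that with all libraries) and -0.14 without 5xFAD fucose replicate 6 (73.6%). An effect of the diet cannot be told apart from these with 6 libraries per group.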

How the results depend on the processing

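Of the alternatives, the pseudocounts, TMM scaling, leaving out the libraries with little Xist and the ribosomal and oxidative phosphorylation score as a covariate were chosen only after the data were seen. edgeR with TMM was planned as the test of raw counts and became an alternative once the unit was known. The total gene count of 5xFAD against WT (402) stayed within 1.5 times under every alternative run, from 343 without 1 library to 562 with DESeq2, and that of 5xFAD on fucose against WT (376) from 277 without 1 library to 507 with DESeq2. The counts of lower genes moved more, from 18 to 85 (31) and from 5 to 76 (17). Without the 3 libraries with little Xist the totals were 352 (323 of them among the 402) and 367 (318 among the 376). The diet count was 0 under every alternative but the fit without a filter, which called 1 gene, Gm21859, chosen after its values were seen: 57 reads in all, in all 6 control-diet and 0 of 6 fucose libraries of 5xFAD (mean 8.91 normalized counts), with an adjusted p of 0.0437. The WT libraries on the same control diet held 1 read of Gm21859 each in replicates 1 and 3 and 0 in the others, so its reads do not follow the control diet alone. Gm21859 was not among the tested genes with the filter, which is why it was not called there. The planned change from TMM to RLE for lists, correlation and share had no separate value, since the deposited factors are RLE factors, and TMM scaling was run in its place. It moved the median change of all genes to 0.0069, -0.011 and -0.0021 in the 3 comparisons.

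The number of called lists depended on the correlation between genes. With an estimated correlation it was 5, 0 and 5 in the 3 comparisons, and with fry 5, 0 and 5, against 15, 3 and 13. The preset correlation of 0.01 was far under the estimates for many lists, such as 0.744 for ribosomal proteins and 0.704 for oxidative phosphorylation. The diet count of 3 also rose to 5 with a replicate block, 7 with 1 surrogate variable, 5 with TMM scaling and 7 without the libraries with little Xist, and it ranged from 2 to 7 with 1 library left out (6 without 5xFAD control replicate 1 or 5 or 5xFAD fucose replicate 2, 3 or 4, 5 without 5xFAD control replicate 3 or 4 or 5xFAD fucose replicate 1, and 7 without 5xFAD fucose replicate 5 or 6). The cause was not tested. With 1 library left out the number of lists ranged from 11 to 17 in the first and from 12 to 16 in the third comparison, and the diet genes stayed at 0. In 5xFAD against WT single libraries ended the calls of heat shock (7 of 12, highest adjusted p = 0.244 without WT control replicate 5), endothelial cells (6, 0.0850 without WT control replicate 2), immediate-early genes (5, 0.324 without 5xFAD control replicate 2), presynaptic release (4, 0.216 without WT control replicate 2) and GABA-A receptors (2, 0.0597 without 5xFAD control replicate 1). Disease-associated and homeostatic microglia, complement, reactive astrocytes and lysosome were called under all 20 alternatives run on lists, in both comparisons with WT.

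The correlation of genotype and diet changes went from -0.42 to -0.045 and the opposite share from 70.1 to 61.2% with the 5xFAD control libraries split into 2 sets of 3. This ended the sharing of libraries, but also left 3 instead of 6 5xFAD control libraries per comparison and a mean of 269 instead of 402 genes in the share, and these were not told apart. A pairing of the samples by replicate number was not shown, nor was it excluded. Same-number correlations of residuals ran from -0.055 to 0.33, -0.167 to 0.0776 and -0.125 to 0.181 between the pairs of groups. In each pair of groups 2 of 6 libraries correlated best with the library of their own number. Blocking on the replicate numbers gave 439, 0 and 412 genes.

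Of 40 named genes called in 5xFAD against WT, 994 of 1076 values under alternatives kept their call, and the 82 that lost it belong to 7 genes (Akr1c14, Lgr6, Hs6st3, Thbd, Hmcn1, Shc3 and Psmb8, with a highest adjusted p with 1 library left out between 0.0664 and 0.121). Of the 22 called in the third comparison, 531 of 593 kept it, and 6 genes lost it in 62 (Btbd17, Igsf21, Nppc, Foxp2, Mlc1 and Sac3d1, between 0.0834 and 0.124). Calls were also gained. In 5xFAD against WT 38 of 1242 values of 46 uncalled genes passed, from 11 genes, among them Ifi27 in 13 alternatives, Tapbp in 6, H2-D1, Ifi27l2a and Ifitm3 in 3 each, Acat2 and Hsph1 in 2 each, and Bst2, Cdh5 and Dlg4 in 1 each. In the third comparison 28 of 566 values of 21 uncalled genes passed, from 9 genes: Aqp4 and Ifi27l2a in 6 each, Fdft1 and Oas1a in 4 each, Atp5d, Rims1 and S100a8 in 2 each, and Fdps and Fuca1 in 1 each. In the diet comparison 0 of 1398 values of 52 genes passed. The signs of 3 values that were not called turned: App in the third comparison (-0.015, from -0.038 with the ribosomal and oxidative phosphorylation score as a covariate to 0.0057 without WT control replicate 6, and -0.032 without WT control replicate 2), and with the ribosomal and oxidative phosphorylation score as a covariate Thy1 (0.031) and Dlg2 (-0.0038) in the diet comparison. The size of some changes moved by over 1.5 times, among them Akr1c14 in the first comparison (-1.82) to -1.21 with a pseudocount of 10. In the diet comparison Arc (-0.79) moved to -0.33 with voom, and Junb (-0.60) and Notch1 (0.53) to -0.19 and 0.25 with the ribosomal and oxidative phosphorylation score as a covariate. Other diet changes ranged widely over the alternatives as well, such as Rpl19 (-0.27 to -0.049), Shank2 (0.060 to 0.32) and Vamp2 (-0.22 to -0.025). Depth limits genes with few reads, such as Fam229a and Plin1, whose group means on fucose lay near the 3 reads that a count of 0 allows.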

Other observations

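The lists below were written down before the data were examined, but the genes named in this part were chosen only after their values were seen. Apoe and Clu, the genes of lipid carriers that are linked to Alzheimer's disease risk, were higher in 5xFAD than in WT on control diet (log2 fold changes 0.77 and 0.47, limma adjusted p = 0.000934 and 0.00248). They were the 2 called members of the 19 in the list of amyloid processing and risk genes. The list as a whole was not called (median -0.046, adjusted p = 0.956), nor with fucose (median 0.075, adjusted p = 0.530). In the unfolded protein response list 1 of 17 members rose, Atf3 (1.08, adjusted p = 0.0133) (list median -0.019, adjusted p = 0.988; with fucose 0.020, adjusted p = 0.945). Markers of resting astrocytes had a median of 0.089, adjusted p = 0.150, with Aqp4 at 0.54, and 0.053, adjusted p = 0.208 with fucose. Oligodendrocyte genes had medians of 0.068, adjusted p = 0.173 and -0.028, adjusted p = 0.530, with Cldn11 and Trf higher in 5xFAD when adjusted over the list alone (0.34 and 0.42), and oligodendrocyte precursors a median of -0.070, adjusted p = 0.533 between genotypes. Excitatory neurons had medians of -0.037, adjusted p = 0.456 between genotypes and -0.044, adjusted p = 0.917 with fucose, and inhibitory neurons -0.12, adjusted p = 0.456 and 0.039, adjusted p = 0.928.

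Markers of brain regions and of tissue at the edge of the brain were not called in 5xFAD against WT on control diet or with fucose. In 5xFAD on fucose against WT on control diet blood and leukocytes were called at the preset correlation, but not with an estimated one (adjusted p = 0.280). With fucose the striatum list had a median of 0.50, adjusted p = 0.0597, hippocampus -0.32, adjusted p = 0.0711, blood and leukocytes 0.56, adjusted p = 0.0548, choroid plexus -0.28, adjusted p = 0.199, meninges and fibroblasts 0.21, adjusted p = 0.199, thalamus and hypothalamus -0.19, adjusted p = 0.690, and cerebellum -0.079, adjusted p = 0.690. The adjusted p-values of lists in this part are camera values at the preset correlation unless stated otherwise. With an estimated correlation the adjusted p was 0.952 each for striatum, hippocampus, and blood and leukocytes. Their scores had exact permutation p-values of 0.312, 0.409 and 0.208. Between genotypes the medians were -0.33, adjusted p = 0.254 for striatum, 0.027, adjusted p = 0.664 for hippocampus, 0.26, adjusted p = 0.283 for blood and leukocytes, 0.21, adjusted p = 0.548 for choroid plexus, -0.20, adjusted p = 0.112 for meninges and fibroblasts, -0.023, adjusted p = 0.525 for thalamus and hypothalamus, and 0.0065, adjusted p = 0.664 for cerebellum. Pericytes and smooth muscle had medians of 0.10, adjusted p = 0.623 between genotypes and 0.025, adjusted p = 0.861 with fucose, and endothelial cells 0.045, adjusted p = 0.410 with fucose. The mitochondrial genome list had medians of -0.078, adjusted p = 0.353 and -0.067, adjusted p = 0.580, glycolysis -0.015, adjusted p = 0.587 and -0.066, adjusted p = 0.199, and nuclear oxidative phosphorylation 0.020, adjusted p = 0.587 between genotypes. The median and the mean differ in sign for thalamus and hypothalamus (mean 0.95), cerebellum (mean -0.16) and unfolded protein response (mean 0.059) between genotypes, and for inhibitory neurons (mean -0.0042) and unfolded protein response (mean -0.023) with fucose. The test of excitatory neurons with fucose pointed up while median and mean were below 0. The first and second principal components of the tested genes held 12.2 and 10.495% of the variance.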
